A study of Drosophila melanogaster with 2 samples.

How the data were processed

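Transcript abundance was measured by RNA sequencing in 2 libraries of Drosophila melanogaster larvae of the third instar, homozygous for the HP1c allele f04929, with the larvae grown at one temperature on one food, per the labels' protocols. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with Illumina protocols. How ribosomal RNA was removed is not given in the sources used here. The labels number the libraries as replicates of one group but do not say whether they came from separate cultures, so the spread between them may be partly technical. The series design speaks of a pair of genotypes. The other genotype was not analysed here, so no change caused by the mutation was computed.

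The authors deposited, for each library, a table of FlyBase transcripts with their length, effective length, TPM and estimated reads. For transcripts above 1 TPM, the deposited TPM equals the estimated reads divided by the effective length, rescaled, to within 0.0315%. Many of the deposited estimated counts are fractional, since reads compatible with several isoforms or gene copies are shared out between them. Some genes with a single transcript, such as HP1c with 25 and 42 reads, have whole counts. The column names, per the file headers, are those written by salmon, but no header or label names the quantifier. The submitters' processing notes name bcl2fastq 2.18.0.12, FastQC, STAR 2.5.2, Picard and HTSeq 0.6.1 without stating a role, and an HTSeq count would not be fractional in this way. The genome build and annotation are not given in the sources used here.

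Each table lists 30119 transcripts, of which 29992 were matched by FlyBase identifier to the Ensembl release 115 annotation of the BDGP6 assembly. Annotated and deposited lengths were equal for 99.8% of them. The other 127 entries, with 0.0981% and 0.110% of the reads of replicates 1 and 2, were left out. TPM and estimated counts were summed per gene, giving 14001 genes, of which 13693 are protein-coding and 308 are pseudogenes. Long non-coding RNAs, such as roX1 and roX2, are not among the matched entries. Coordinates are 1-based positions of that annotation on BDGP6. Exon overlap between genes on either strand was taken from the same annotation. The strandedness of the libraries is not given in the sources used here, so reads of overlapping genes on opposite strands may not have been separated. No genome sequence was used, and near-identical copies were recognised only by name or position.

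Replicate 1 held 39745145 and replicate 2 held 45177298 estimated reads. At this depth, 3 reads on a transcript of 1000 bases correspond to 0.0993 TPM in replicate 1 and 0.0755 TPM in replicate 2. Intervals at the 95% level are exact Poisson intervals for the TPM of a gene, Wilson intervals for shares of reads, and exact Clopper-Pearson intervals for a ratio between libraries. All of these cover counting error only, and reads without molecular identifiers are not independent molecules. A ratio against a library with 0 reads was computed against a floor of 3 reads in that library and is given as a lower bound.

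With 1 group of 2 libraries there is no test over replicates between groups, and no p-value is reported. Levels are means ± SD over the 2 libraries. Ratios between libraries compare these 2 libraries of one genotype and not conditions. Estimated counts were rounded to whole reads and scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3. A gene was counted as differing when it had a mean of at least 10 reads, a ratio of at least 2 and an interval that excluded 1. Log2 ratios, replicate 2 over replicate 1, were computed with 0.5 reads added. A gene was called detected at 1 TPM or more in both libraries. Correlations across genes used log2(TPM + 1). The biological coefficient of variation was estimated with edgeR for the group as a whole. The calls were tested on simulated Poisson counts with the means and library sizes of the 14001 genes. In that simulation 98 of 100 genes set 3-fold apart and 100 of 100 set 8-fold apart were recovered, and 17 of 12008 unchanged genes were called. The simulation held counting error only. It does not give the rate of calls expected from the spread between the real libraries, whose biological coefficient of variation was 25.3%.

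Gene lists for tissues, pathways and complexes were fixed before the data were examined, 30 in all, and 567 of their 569 symbols were measured. A few older symbols were matched through synonyms. For each list the median log2 ratio was placed among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression. This percentile describes the 2 libraries. In the simulation, where genes varied independently, 5 of 200 unchanged lists fell outside the central 95%. Genes regulated together can move as one between libraries, which neither the simulation nor the random lists reproduce. The genes named were also fixed by rule: all members of the HP1 family and HP1c partner lists, the 20 most abundant genes apart from rRNA, the 10 largest ratios in each direction among genes with at least 100 reads in total, and up to 4 most abundant members of each other list. Genes beside HP1c were chosen by position. Any other gene is named as one chosen after its values were seen.

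The alternatives were CPM or TMM-scaled CPM in place of TPM, library size alone or DESeq2 1.42.0 size factors in place of TMM, other minimum reads, folds, pseudocounts and detection thresholds, single transcripts in place of genes, and each library alone. TPM rescaled without the rRNA entries, genes without exon overlap, and ratios corrected for transcript length were added after the data were seen. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.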

Results

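Larvae of the third instar homozygous for HP1c f04929 were profiled in 2 libraries. HP1c encodes one of the heterochromatin protein 1 paralogs of the fly, chromodomain proteins that bind methylated histone H3. The series was designed to compare gene expression between this mutant and another genotype, which was not analysed here. The data therefore give the transcriptome of the mutant larvae and its spread between replicates. Of 14001 genes, 10900 (77.9%) reached 1 TPM in both libraries, which held 39745145 and 45177298 estimated reads. Entries annotated as rRNA pseudogenes took 12.13% of the reads of replicate 1 (95% Wilson interval 12.12% to 12.14%) and 2.551% of replicate 2 (2.546% to 2.555%).

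HP1c was among the least abundant members of its own family in these larvae. Its level was 0.842 TPM (95% interval 0.545 to 1.24) in replicate 1, from 25 reads, and 1.08 TPM (0.775 to 1.45) in replicate 2, from 42 reads. The mean was 0.959 ± 0.165 TPM (SD, n = 2). HP1c lay below the detection threshold of 1 TPM in replicate 1. In replicate 2 it lay at the 0.626th percentile of the genes at 1 TPM or more in that library. The gene of HP1a (FBgn0003607), the main heterochromatin protein of the family, stood at 192 ± 13.8 TPM, and HP1b at 31.1 ± 0.122 TPM. Within a library, HP1c came to 0.497% ± 0.0503 of the HP1a level and 3.08% ± 0.543 of the HP1b level (SD, n = 2). These values do not say whether HP1c was lowered by the allele, since no control was analysed.

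The HP1c gene (FBgn0039019) lies on chromosome 3R at 22745620 to 22746605 of BDGP6, on the plus strand, and has an annotated exon overlap with CG17141. CG17141 (3R, 22746446 to 22747599, minus strand) stood at 7.09 ± 0.207 TPM. The HP1c value sums all reads assigned to its transcript, so the part of the gene they came from, and whether some came from CG17141, cannot be read from it. On the other side, vret (3R, 22742954 to 22745581) stood at 3.55 ± 0.307 TPM and Dcr-1, which makes microRNAs, at 4.89 ± 0.204 TPM.

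The other HP1-like genes were expressed at low levels. HP1D3csd stood at 5.57 ± 1.80 TPM, HP6 at 3.77 ± 0.644, HP1Lcsd at 2.14 ± 0.281 and HP1e at 1.80 ± 0.481 TPM. The least abundant was rhi, which encodes the germline protein Rhino, at 0.256 ± 0.171 TPM. It was the one family member that differed at least 2-fold between the libraries, from 19 reads in replicate 1 and 9 in replicate 2 (2.73-fold, interval 1.18 to 6.86). All 7 genes listed as HP1c partners were detected, and none differed 2-fold between the libraries. Transcripts of the zinc finger proteins that bind HP1c stood at 31.2 and 28.1 TPM in replicates 1 and 2 for woc and at 22.9 ± 0.739 TPM for row. Ubqn, a ubiquilin, reached 72.8 ± 1.24 TPM. The FACT subunit genes Ssrp and dre4 stood at 27.7 ± 3.33 and 31.3 ± 3.61 TPM, and the interband protein genes pzg and Chro at 41.4 ± 1.46 and 27.5 ± 1.82 TPM.

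**Figure D1:**
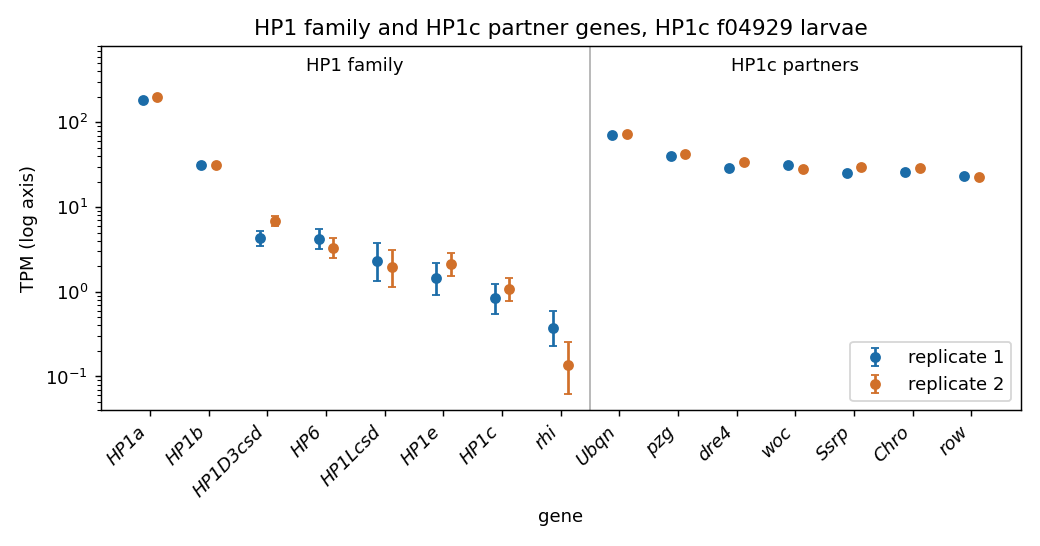
TPM on a log axis of HP1 family and HP1c partner genes in replicate 1 (blue) and replicate 2 (orange), with exact Poisson 95% intervals of the reads as bars. HP1c lies at 0.842 and 1.08 TPM, below HP1b at 31.1 TPM and HP1a at 192 TPM, while every partner gene lies above 20 TPM.

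Apart from rRNA, the most abundant transcripts were of genes known from the salivary glands, fat body, cuticle, gut and mitochondria. The 10 most abundant entries of each library, rRNA included, took 21.7% ± 1.17 of the TPM (SD, n = 2), and 3 of the 10 were rRNA entries in replicate 1 against 0 in replicate 2. With rRNA left out and TPM rescaled, an alternative added after the data were seen, the 10 most abundant genes took 19.1% in replicate 1 and 22.9% in replicate 2. The salivary glue gene Sgs7 stood at 44416 ± 20806 TPM, and the glue genes Sgs5 and Sgs3 at 7593 ± 3190 and 7099 ± 3478 TPM. The larval serum protein and fat body list was represented by Fbp2 at 9787 ± 467, Lsp2 at 8546 ± 13.0 and Fbp1 at 7636 ± 3047 TPM. The larval cuticle genes Lcp1 and Lcp4 stood at 9600 ± 3168 and 6516 ± 2512 TPM, and the gut serine proteases Jon65Aiv and Jon99Cii at 7387 ± 1729 and 5447 ± 1127 TPM. Of the odorant-binding family, Obp99b reached 12519 ± 972 TPM. The translation factor gene eEF1alpha1 stood at 6223 ± 142 TPM. CG34166, CG42586 and CG42500, also among the 20 most abundant, stood at 22650 ± 5999, 9251 ± 362 and 8890.0 ± 10.7 TPM. The mitochondrial genes mt:ATPase8, mt:CoIII, mt:CoI, mt:ATPase6 and mt:CoII stood at 53798 ± 5970, 19108 ± 71.2, 8431 ± 492, 8033 ± 886 and 7437 ± 1226 TPM. TPM divides reads by effective length, so very short transcripts such as mt:ATPase8 rank higher by TPM than by reads.

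Other tissues were measurable at lower levels. All 14 muscle genes were detected, led by Act57B at 564 ± 58.4 TPM, as were all 13 imaginal disc genes, led by sd and ci at 36.2 ± 0.634 and 35.9 ± 3.09 TPM. Of 13 neuronal genes, 11 were detected, with Syt1 at 37.8 ± 1.01 and elav at 13.8 ± 1.98 TPM. All 10 haemocyte genes were detected, with He at 67.8 ± 14.9 TPM. Spermatocyte genes were present, 18 of 20 at 1 TPM or more in both libraries, with Mst84Da at 83.0 ± 2.30 and Mst87F at 79.6 ± 7.16 TPM. The yolk and chorion genes of adult females were all under 1 TPM, as were the 11 Y-linked genes in at least one library. All 10 genes of the heterochromatin factor list were detected, among them JIL-1 at 16.8 ± 1.55 and wde at 13.4 ± 0.677 TPM. The cytosolic ribosomal protein genes held 13.9% and 14.0% of the TPM in replicates 1 and 2.

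By chromosome arm, genes on chromosome 4, the small arm rich in heterochromatin, had the highest median level of the nuclear arms. Of its 86 genes, 77 (89.5%) were detected, with a median of 27.5 ± 0.440 TPM (SD of the library medians, n = 2). The medians of detected genes were 12.8 ± 0.199 TPM on 2L, 13.4 ± 0.596 on 2R, 13.9 ± 0.305 on 3L, 12.6 ± 0.289 on 3R and 11.9 ± 0.773 on X. On Y, 9 of 80 genes were detected. Genes are not replicates, and no test between arms was made. Chromosome 4 genes did not stand apart between the libraries, with a median log2 ratio of -0.03 and 1 gene at least 2-fold higher in each.

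The replicate libraries were then compared, to measure the spread within the mutant group. Most genes had near-equal levels. Over the 12203 genes with a mean of at least 10 reads, the quartiles of the log2 ratio, replicate 2 over replicate 1, were -0.19 and 0.19. Across these genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.973 and Spearman's rho 0.973. The biological coefficient of variation was 25.3%. The chi-square statistic of the reads over genes was 419 times its degrees of freedom, so the files do not hold one library in duplicate. At least 2-fold differences were found for 662 genes (5.42%), of which 501 were higher in replicate 1 and 161 in replicate 2. The rRNA entries were 15 of the 501. With library size alone as the scaling, the split was 394 and 276, because the median log2 ratio of all genes then moved by 0.19.

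**Figure D2:**
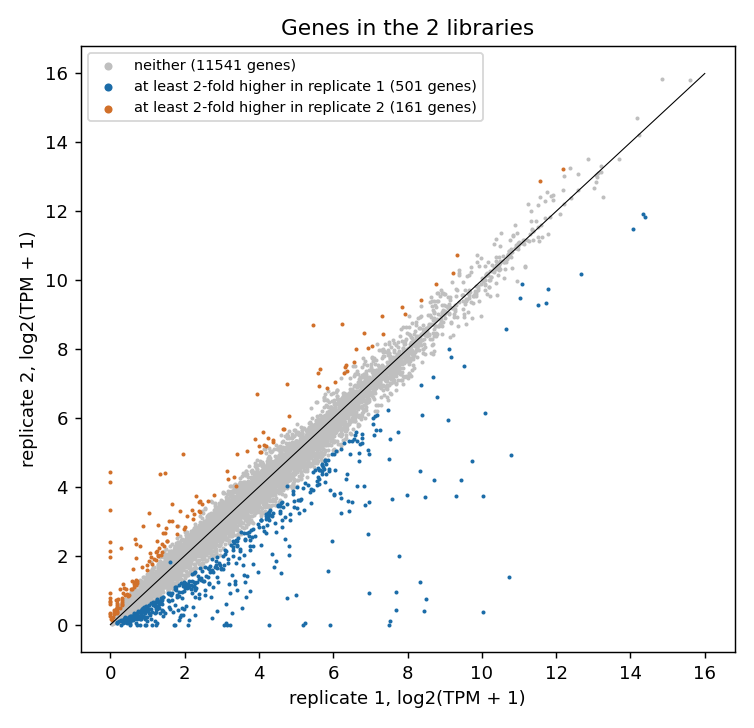
Levels of the 12203 genes with a mean of at least 10 reads in replicate 1 (x axis) and replicate 2 (y axis), as log2(TPM + 1), with the line of equal TPM. Blue points are the 501 genes at least 2-fold higher in replicate 1, and orange points the 161 higher in replicate 2, after TMM scaling of the reads.

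The genes with the largest ratios towards replicate 1 lay in part in chromosomal clusters. Eig71Ec and Eig71Ed, ecdysone-induced genes of a cluster on 3L (15651479 to 15653096), had 3226 and 3307 reads in replicate 1 against 2 and 4 in replicate 2. Their ratios were 2088-fold (interval 578 to 17248) and 1070.2-fold (418 to 3930). Eig71Ef, in the same cluster, had 574 reads against 0, at least 248-fold. The neighbouring genes CG7924 and CG34244 (3L, 14233469 to 14235941) had 56232 and 13737 reads against 70 and 9, ratios of 1039.8-fold (823 to 1334) and 1976-fold (1040.5 to 4322). CG32762 (X, 5500208 to 5501229) had 4288 reads against 0, at least 1850.4-fold. PGRP-SB2, of the peptidoglycan recognition protein family, had 680.0 reads against 0, at least 293-fold.

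Towards replicate 2, TotZ, a Turandot stress gene, had 389 reads against 23 (13.1-fold, interval 8.58 to 20.9). The neighbouring genes CG8087 and CG14852 (3R, 14564323 to 14566513) were 11.5-fold (7.402 to 18.9) and 10.5-fold (7.76 to 14.6) higher, of which CG14852 has exon overlap with CG31313, and CG11300 (2R, 23751915 to 23752495) was 9.84-fold (9.10 to 10.7) higher in replicate 2. The remaining extreme genes had 0 reads in one library and are uncertain, since reads may be assigned between copies or overlapping models. The histone copies His2B:CG33872 (289 reads against 0) and His2B:CG33870 (0 against 342) showed opposite patterns. So did CG32939 (292 against 0) and CG18542 (0 against 476), which have exon overlap with Unc-115a and Unc-115b. Adhr (0 against 103) overlaps Adh, att-ORFB (349 against 0) overlaps DPCoAC, CG18170 (0 against 232) overlaps CG13926 and CG33791, and CG32152 (0 against 111) overlaps CG5151. CG32857 (0 against 881) has no annotated exon overlap.

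Of the 30 gene lists, 11 had a median ratio outside the central 95% of matched random lists. If genes varied independently, 1.5 would be expected, but members of one list may move together, so the excess does not measure chance. The salivary gland list stood furthest towards replicate 2, with a median log2 ratio of 0.93 against a random range of -0.20 to 0.12. Of its 14 members with enough reads, 4 were at least 2-fold higher in replicate 2 and none in replicate 1. Sgs4 was 2.55-fold (interval 2.53 to 2.57) and Sgs3 2.10-fold (2.08 to 2.11) higher, while Sgs7 at 1.96-fold and Sgs5 at 1.86-fold stayed under 2-fold. The list took 5.02% of the TPM in replicate 1 and 10.01% in replicate 2. The gut digestive enzyme list had a median log2 ratio of 0.40 (random range -0.14 to 0.08), with 24 of 29 members above 0. Its most abundant members Jon65Aiv, Jon99Cii, Jon65Aiii and deltaTry had log2 ratios of 0.50, 0.45, 0.57 and 0.60.

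The ecdysone response list stood towards replicate 1, with a median log2 ratio of -0.55 (random range -0.20 to 0.09). Of its 19 members, 6 were at least 2-fold higher in replicate 1 and none in replicate 2. ImpE2, an ecdysone-inducible imaginal disc gene, stood at 572 and 219 TPM in replicates 1 and 2 (2.57-fold, interval 2.52 to 2.62). The broad gene br stood at 233 and 148 TPM, and the receptor gene EcR at 109 and 104 TPM. MsrA went the other way, at 163 and 178 TPM, and 5 of the 19 members had log2 ratios above 0. The ecdysone synthesis list did not stand apart, with a median log2 ratio of -0.14 (random range -0.25 to 0.25). The fat body list had a median log2 ratio of -0.31 (random range -0.22 to 0.18) with no member past 2-fold. Fbp1 stood at 9790 and 5482 TPM, while Lsp2 stood at 8537 and 8555 TPM.

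The antimicrobial and immune list stood furthest towards replicate 1, with a median log2 ratio of -1.90 (random range -0.20 to 0.22). Of 16 members with enough reads, 10 were at least 2-fold higher in replicate 1 and none in replicate 2. The antifungal peptide gene Drs stood at 441 and 96.1 TPM in replicates 1 and 2 (4.61-fold, interval 4.31 to 4.94). The peptide gene Mtk stood at 85.2 and 8.84 TPM (9.84-fold, 7.31 to 13.5), and PGRP-SB1 at 102 and 25.9 TPM (3.90-fold, 3.55 to 4.30). Rel, which encodes the NF-κB factor of the immune deficiency pathway, was at 50.7 and 48.0 TPM. The oxidative stress and detoxification list had a median log2 ratio of -0.23 (random range -0.17 to 0.14), with 3 of 20 members at least 2-fold higher in replicate 1. Among its most abundant members, Prx6b stood at 204 and 126 TPM, GstD1 at 625 and 552 TPM and Cat at 315 and 249 TPM. Sod1 stood at 316 and 315 TPM, and 7 of the 20 members had log2 ratios above 0.

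Smaller shifts towards replicate 2 were seen for 5 more lists. The median log2 ratio was 0.36 for the stress and Turandot list, 0.26 for neurons, 0.22 for haemocytes, 0.16 for heat shock and 0.15 for the cell cycle. None of the 13 neuronal, 10 haemocyte or 18 cell cycle genes reached 2-fold. In the stress list, TotC stood at 14.4 and 102 TPM in replicates 1 and 2 and TotA at 507 and 771 TPM. Of its 9 members with enough reads only 5 were above 0, with 2 at least 2-fold higher in replicate 2 and 1 in replicate 1. The heat shock list went both ways, with 3 members at least 2-fold higher in replicate 1, among them Hsp23 at 2180 and 948 TPM, and 2 higher in replicate 2. The other 19 lists lay within the random range. Among these, the testis list had a median log2 ratio of 0.01 with 0 of 20 genes past 2-fold, and the cytosolic ribosomal protein list a median of 0.03 with 0 of 91. The heterochromatin factor list had a median of -0.04 with 0 of 10 past 2-fold, and the HP1 family list 0.10 with 1 of 8. The larval cuticle list had a median of -0.10 with 3 of 11 genes at least 2-fold higher in replicate 1, and the muscle list -0.17 with 2 of 14. Imaginal disc and glial genes, with medians of -0.14 and -0.16, had no member past 2-fold. The imaginal disc list lay only just within the random range, at the 2.7th percentile, and 0 of its 13 members had log2 ratios above 0. Of the 7 glial genes, 2 were above 0.

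**Figure D3:**
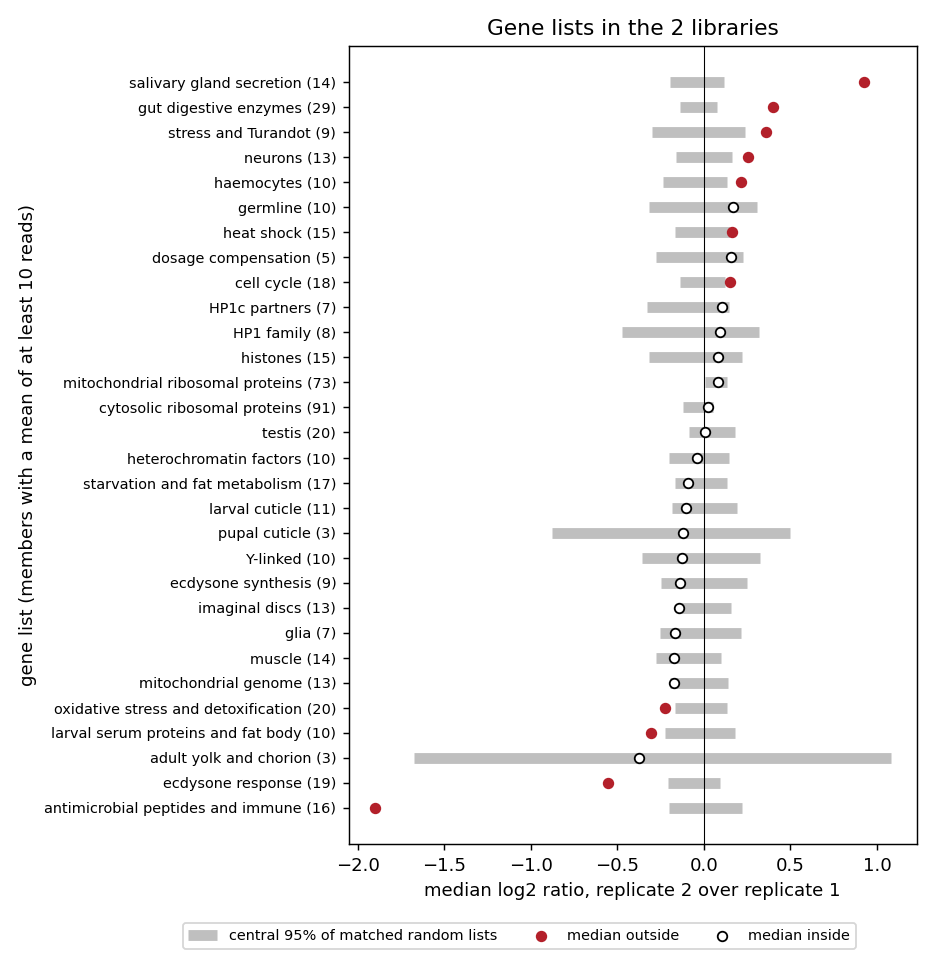
Median log2 ratio of replicate 2 over replicate 1 for each of the 30 gene lists (points; number of members with a mean of at least 10 reads in brackets) and the central 95% of 10000 matched random lists (grey bars). Filled points are the 11 lists outside their bar, from -1.90 for antimicrobial and immune genes to 0.93 for salivary gland secretion.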

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

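The 2 libraries are one group, so an adequate spread between independent animals could not be estimated, and depth limits the values of genes with few reads such as HP1c (25 and 42 reads). No paired analysis was possible because there is only 1 group. Leaving out a library is not defined for the correlations or the ratios between libraries, which need both. With each library alone, HP1c ranged from 0.842 to 1.08 TPM, its share of the HP1a level from 0.462% to 0.533%, the genes detected from 11029 to 11119, the share of the 10 most abundant entries, rRNA included, from 20.9% to 22.6% (without rRNA 19.1% and 22.9%) and the chromosome 4 median from 27.1 to 27.8 TPM.

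In other units HP1c stood at 0.780 CPM and 0.772 TMM-scaled CPM, and the 10 most abundant entries took 15.6% of the reads (19.3% and 11.9% in replicates 1 and 2, with 4 and 1 rRNA entries among them) against 21.7% of the TPM. Without rRNA the mean share of TPM was 21.0%. Detection thresholds of 0.5 and 5 TPM gave chromosome 4 medians of 25.1 and 34.1 TPM. Pearson's r was 0.967 with a pseudocount of 0.1, 0.980 without a filter on reads and 0.966 at a mean of at least 100 reads, and Spearman's rho was 0.980 and 0.967 under the latter 2 settings. The 662 genes at least 2-fold apart (501 and 161 by direction) became 383 (296 and 87) at a mean of at least 100 reads, where fewer genes are tested. A 1.5-fold threshold gave 1490 genes (958 and 532) and a 4-fold threshold 203 (164 and 39). With library size alone the 670 genes split into 394 and 276, and 555 genes were shared with TMM scaling. Single transcripts gave 4582 of 23627 past 2-fold (2481 and 2101), so estimated isoform values differ between the libraries far more often than gene sums. The intervals do not cover error in sharing reads between isoforms, so how much of this excess comes from that error was not tested. DESeq2 size factors gave 508 and 153, and no filter 557 and 176. A scaling moves all log2 ratios alike (by 0.19 with library size alone, -0.02 with DESeq2 size factors), so the number of lists outside the random range does not test it. With library size alone the median of the oxidative stress list was -0.04 in place of -0.23, of the fat body list -0.12 for -0.31, of the cell cycle list 0.34 for 0.15 and of the heat shock list 0.35 for 0.16. No list outside the random range changed sign.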

Other observations

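Gene families were also compared, some of which, such as Sgs and Jon, hold genes of the lists above and are not separate evidence. Families were formed by shared symbol stems from the genes with a mean of at least 10 reads. Of 121 families with at least 6 such members, 18 lay outside the random range. If genes varied independently, 6.05 would be expected. They were examined after the data were seen, and the genes named in this paragraph were chosen for their values. In the Eig71E cluster of ecdysone-induced genes, 6 of the 7 members with enough reads were at least 2-fold higher in replicate 1. Members with too few reads were not counted. Eig71Ee, a salivary gland gene of the same cluster, was 1.99-fold higher in replicate 2. The tyrosine hydroxylase gene ple stood at 843 and 26.1 TPM in replicates 1 and 2, and ebony (symbol e; 3R, 21229839 to 21237177), of the same tanning pathway, at 361 and 0.685 TPM. Of 42 Cpr cuticle protein genes with enough reads, 13 were at least 2-fold higher in replicate 1 and 1 in replicate 2, with a median log2 ratio of -0.37. The Lcp cuticle protein family went the other way, with a median of 0.41 and 6 of 9 members above 0, although its 1 member past 2-fold was higher in replicate 1. The chitinase family Cht had a median of -0.48. Ilp8, the disc-derived relaxin-like hormone, stood at 57.5 and 1.97 TPM. The proteasome regulatory subunit family Rpn had a median of -0.30, and the translation initiation family eIF a median of 0.10.

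The checks of library scaling, transcript length and exon overlap were chosen after the data were seen, and the second lists were written before their own values were computed. For the 662 genes at least 2-fold apart, library scaling moves all genes alike and cannot by itself widen the ratios between genes. The count of 161 in the smaller direction was known beforehand and is no separate test. The split by direction depended on the scaling, with 394 and 276 for library size alone. As whole causes of these calls, transcript length and overlapping models are argued against. Of the calls, 94.7% stayed after the median of genes of like length was removed. Genes without exon overlap passed 2-fold at 116% of the rate of all genes. Spearman's rho of transcript length and log2 ratio was -0.18. The random lists were matched on expression and not on length, so a part of length in the smaller list shifts was not tested. A hypothesis is that the animals of replicate 1 were on average nearer to puparium formation. A second list of 20 late larval ecdysone pulse genes went that way (median log2 ratio -0.40, at the 0.01st percentile of matched random lists), with 5 members at least 2-fold higher in replicate 1. Both ecdysone lists hold genes that respond to one hormone, so the second does not separate timing from other causes of their shift. A second list of 22 feeding midgut genes was predicted to lie towards replicate 2 and did the opposite (median -0.35, percentile 0, the lowest that 10000 lists can give), with 7 members at least 2-fold higher in replicate 1 and 0 in replicate 2, while the gut digestive enzyme list had a median of 0.40 with 24 of 29 members above 0, so gut genes did not move as one. The labels give no age within the instar, no biological explanation was tested by design, and reads shared between near-identical copies stay open, so timing may be a source of part of the spread and remains a hypothesis.

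The higher antimicrobial peptide transcripts of replicate 1 could come from a humoral response of the Toll pathway. A list of Bomanins and other Toll targets had a median log2 ratio of -0.07, at the 31.4th percentile of matched random lists (random range -0.31 to 0.26), over 10 members with enough reads. Of these, 2 were at least 2-fold higher in replicate 2 and 1 in replicate 1. As a set, these 10 genes did not share the antimicrobial list's median of -1.90. That argues against a shift of all Toll targets as its whole source. The list was low, with a median of 0.231 CPM over its 19 measured members, so a part of Toll in the antimicrobial shift stays open. Of the 19 measured members 8 were detected, and nothing is said of those with too few reads. Both libraries belong to one group, so no biological explanation was tested by design.

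HP1c reads were few in both libraries, and the overlapping CG17141 had 234 and 321 reads against 25 and 42 for HP1c. Of the 662 genes past 2-fold, 32 had 0 reads in 1 library, and 17 of these overlap another gene. CG33502 (X, 21609357 to 21611526), chosen after its values were seen, had 251 reads in replicate 1 and 0 in replicate 2, the reverse of CG32857 (X, 21615449 to 21617617).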
